A study of Sus scrofa with 64 samples.

How the data were processed

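RNA sequencing of mid-jejunum mucosal scrapings from 64 female piglets was used, with 1 library per pig and 16 pigs in each of 4 groups (fed and fasted at 4 and at 6 weeks of age). Per the labels, the intestine was rinsed, the mucosa was scraped with glass slides and frozen, and total RNA was sequenced on a BGISEQ-500. The extraction protocol speaks of frozen muscle tissue, which was taken here as a carry-over in the wording and could not be checked. The deposited values were raw counts per gene, made with STAR and HTSeq on Sscrofa11.1 per the submitters' processing notes. Versions, the annotation release, the strand setting and read filters were not given in the sources used here, so reads of overlapping genes on opposite strands could not be assigned by strand.

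Each library gave counts for 31908 gene IDs and 5 HTSeq summary classes, which were left out of library sizes and tests. Of all classes of reads in a library, reads outside annotated genes came to 4.84 to 8.89%, ambiguous reads to 5.5 to 7.64% and reads without a unique alignment to 2.73 to 4.07%. Library totals were 18774144 to 21159989 counts, with 16978 to 18961 genes counted per pig. Symbols were paired with 15029 IDs, and 16879 IDs had none, with 86.0% of the counts on IDs with a symbol. No 2 libraries of a group were identical. The median chi-square ratio between libraries of a group, which is 1 for sampling noise alone, was 61.05 in fed 4-week, 106.7 in fasted 4-week, 100.2 in fed 6-week and 100 in fasted 6-week piglets. The sources gave no litter, pen, day of sampling or sequencing batch, so none was modelled, and RNA integrity values were not used here. Each odd pig number and the next even number held 1 fed and 1 fasted pig of the same age. The sources did not say whether such neighbours shared a litter or pen. No paired analysis was run, so all tests treat the pigs as unmatched.

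Groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Genes were kept by filterByExpr of edgeR, which left 14062 of the 25772 with a count in any pig. Libraries were scaled by TMM (factors 0.758 to 1.383), with mean factors of 0.901 ± 0.06 in fed 4-week, 1.049 ± 0.141 in fasted 4-week, 1.045 ± 0.068 in fed 6-week and 1.027 ± 0.076 in fasted 6-week piglets. All 64 pigs entered 1 edgeR model with a mean per group, robust dispersions (common biological coefficient of variation 0.289) and robust quasi-likelihood F tests. The comparisons were fasted against fed at each age, the difference between those, and 6 against 4 weeks within fed and within fasted piglets. Adjusted p values are Benjamini-Hochberg values over 14062 genes within a comparison, with calls at an adjusted p under 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of F. CPM values use TMM-scaled libraries, and ± gives the SD over 16 pigs. Counts such as 16 of 16 piglets give the pigs beyond the median of the other group.

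Of 46 gene lists written in advance, 42 had at least 5 measured members and were tested (26 pathway and 16 cell type lists). The other 4, for neutrophils, erythrocytes, adipocytes and pancreatic acinar cells, had 3, 4, 3 and 3 measured members. Lists were tested on log2 CPM with camera at a preset correlation of 0.01, adjusted over 42 lists, and again with an estimated correlation and with fry. Cell type marker levels per pig, the mean log2 CPM over a list, were compared by 2-sided permutation tests with 100000 resamples, adjusted over 64 tests, with a smallest possible p of 1e-05.

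Named genes followed a fixed rule. For each comparison these were the 5 largest rises and the 5 largest falls among called genes with a symbol and a mean log2 CPM of at least 1, other than immunoglobulin, T cell receptor, mitochondrial and ribosomal protein genes. To these were added the 2 members with the smallest p in each of up to 8 called lists with the smallest camera p. The third part was genes given whatever their result, among them SI, APOA4, PCK1, CPT1A, SLC5A1, SLC15A1, LGR5, MUC2, LCT and MKI67. LCT and MKI67 had no paired ID. Some genes that the rule named are not reported here. Locations came from a reference table on Sscrofa11.1 and were matched by symbol.

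The alternatives fixed in advance were DESeq2 size factors, scaling by library size alone, no filter, DESeq2, limma-voom, a test against a 1.5-fold threshold, 5 surrogate variables, smooth muscle and B cell marker levels as covariates, and fits of 2 groups only. Fits without fasted 4-week pigs 1, 28 and 32, which had the lowest limma-voom sample weights (0.25, 0.34 and 0.36), and without fed 4-week pig 15 for CYP1A1 were added after the data were seen. Fits without fasted 6-week pig 45 for IFIT2 and without fasted 6-week pig 41 for DTNA were also added then. Other splits of the pigs were drawn 100 times per comparison, the real one included.

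The method was tested on simulated data of 14062 genes with 50 genes changed at each fold. At 1.25-, 1.5-, 2- and 4-fold it recovered 34, 66, 92 and 100% for fasting at 4 weeks, 28, 70, 90 and 98% for fasting at 6 weeks, 8, 48, 70 and 94% for the difference between ages, 26, 68, 80 and 100% for age in fed and 24, 74, 92 and 98% for age in fasted piglets. False calls were 1.3, 6.9, 6.7, 6.7 and 5.1% of the calls in that order. A lowered list was called in each case, with 0 others. The simulated genes varied independently of each other, so this could not test how the list calls fare when members vary together. Far fewer genes were changed than were called in the real data, so the rates of recovery and false calls need not hold there. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.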

Results

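RNA from mucosal scrapings of the mid-jejunum was sequenced for 64 female piglets of a Large White × Norwegian Landrace cross. There were 4 groups of 16: fed and fasted piglets at 4 weeks of age, and fed and fasted piglets at 6 weeks. Fasting lasted 48 h with free access to water. Fed 4-week piglets stayed with the sow on the farm, and fasted 4-week piglets were moved to a separate pen there. The 6-week piglets had been moved at 4 weeks of age to a research facility, housed in pairs and given a weaning diet for 2 weeks, so age, weaning, diet and housing changed together. Libraries held 18774144 to 21159989 counts, and 14062 genes were tested.

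On the first principal component, which held 30.6% of the variance, fed 4-week piglets lay apart from the other 3 groups. Levels are given as CPM, counts scaled to library sizes adjusted by TMM factors. The 10 most abundant genes took 17.847 ± 1.502% of the gene counts in fed 4-week piglets (mean ± SD, n = 16), against 10.958 ± 2.059% in fasted 4-week, 11.642 ± 2.308% in fed 6-week and 12.958 ± 2.031% in fasted 6-week piglets. Reads outside annotated genes made up, of all classes of reads, 5.326 ± 0.331% in fed 4-week piglets, 6.825 ± 0.661% in fasted 4-week, 6.931 ± 0.534% in fed 6-week and 7.216 ± 0.584% in fasted 6-week piglets.

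**Figure D1:**
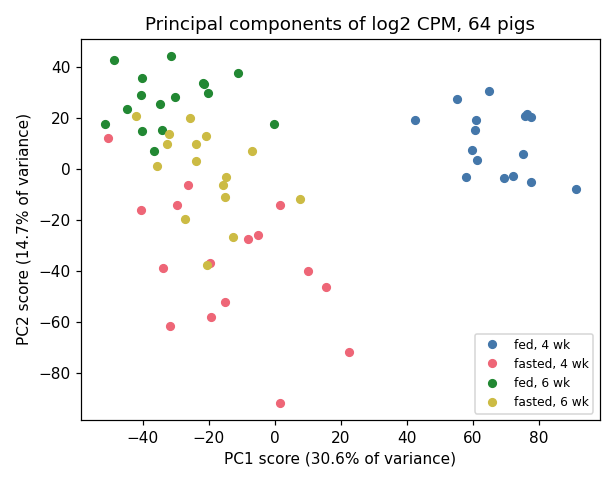
Principal components of log2 CPM, with each point a pig coloured by group; the first component holds 30.6% and the second 14.7% of the variance. Fed 4-week piglets sit apart from the other 3 groups along the first component.

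The question of the first comparison was what 48 h without milk or feed changed in the jejunum of 4-week piglets. In fasted piglets most interferon-stimulated, cell cycle and ribosome assembly genes rose, as did antigen presentation genes by smaller amounts. Most genes for packaging and burning dietary fat, for the respiratory chain and for mineral uptake fell, and so did markers of smooth muscle, fibroblasts and blood vessels. None of these list calls held with an estimated correlation. Of 14062 genes, 4768 rose and 4141 fell, and 1358 of the rises and 992 of the falls were at least 2-fold. With scaling by library size alone 6960 rose and 2518 fell, and the median gene was at 0.25 on the log2 scale, against 0.03 with TMM.

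Interferon-stimulated genes made the strongest group at 4 weeks: 28 of 29 measured members rose and 0 fell, with a median log2 fold change of 2.89 (camera adjusted p = 1.3e-19, adjusted p = 0.53 with an estimated correlation). IFI44L, an antiviral effector, rose from 93.9 ± 20.5 to 362 ± 69.2 CPM (mean ± SD, n = 16, log2 fold change 1.95, SE 0.14, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.8e-19), and 16 of 16 fasted piglets lay above the fed median. The largest rises included the antiviral OASL (4.65 ± 3.59 to 443 ± 219 CPM, log2 fold change 6.57, SE 0.56, adjusted p = 5.3e-16), the antiviral IFIT2 (5.67, SE 0.66, adjusted p = 5e-11) and the lymphocyte-attracting chemokine CXCL11 (1.01 ± 0.909 to 126 ± 87.7 CPM, log2 fold change 6.94, SE 0.54, adjusted p = 2e-17), in 16 of 16 piglets each. CXCL11 (ENSSSCG00000008978) is a protein-coding gene on chromosome 8, 71713790 to 71725669 of Sscrofa11.1, matched by symbol. The stress-response regulator NUPR1 rose by 5.99 (SE 0.47, adjusted p = 3.5e-17), and CCR7, the lymph-node homing receptor, rose by 5.83 (SE 0.41, adjusted p = 3e-19). Averaged over the interferon list, log2 CPM was 5.59 ± 0.36 in fed and 8.53 ± 0.64 in fasted 4-week piglets.

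Genes of antigen presentation rose with them: 8 of 13 rose and 0 fell. Their median log2 fold change was 0.51 (camera adjusted p = 0.0005, adjusted p = 0.53 with an estimated correlation). TAP1, which carries peptides into the endoplasmic reticulum, rose from 166 ± 49.7 to 724 ± 236 CPM (log2 fold change 2.13, SE 0.16, adjusted p = 2.2e-18), and the immunoproteasome subunit PSMB8 rose by 1.66 (SE 0.12, adjusted p = 2.3e-18). Of 10 cytotoxic lymphocyte markers, 8 rose and 0 fell. Members had a median log2 fold change of 0.83 (camera adjusted p = 0.013, adjusted p = 0.53 with an estimated correlation), and of 0.50 with smooth muscle and B cell marker levels as covariates. Marker levels averaged per pig rose by 0.77 on the log2 scale for cytotoxic lymphocytes (permutation test, 2-sided, adjusted p = 0.00012), by 0.55 for T cells (adjusted p = 0.0014), by 0.85 for plasma cells (adjusted p = 0.00049) and by 0.86 for macrophages and dendritic cells (adjusted p = 0.00018).

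Proliferation genes rose in fasted 4-week piglets. Of 29 cell cycle genes, 28 rose and 0 fell. As a group they had a median of 1.34 (camera adjusted p = 1.2e-06, adjusted p = 0.53 with an estimated correlation). The rise was not uniform, since the mean log2 CPM of the list ranged from 2.54 to 5.37 in fasted and from 2.45 to 3.65 in fed piglets. Examples were the kinetochore gene CENPF (8.08 ± 2.94 to 38.0 ± 13.6 CPM, log2 fold change 2.23, SE 0.2, adjusted p = 6.7e-15, 16 of 16 piglets) and the mitotic kinase CDK1 (1.65, SE 0.2, adjusted p = 1.9e-10, 15 of 16). Of 26 ribosome assembly genes, 25 rose and 0 fell. The median of the group was 0.93 (camera adjusted p = 1.2e-06, adjusted p = 0.53 with an estimated correlation). Examples were the growth regulator MYC (17.5 ± 7.43 to 61.7 ± 24.5 CPM, log2 fold change 1.82, SE 0.19, adjusted p = 1.1e-12) and the nucleolar chaperone NPM1 (1.04, SE 0.12, adjusted p = 2e-11). Crypt stem cell markers rose in 14 of 17 and fell in 2. Their median log2 fold change was 1.45 (camera adjusted p = 0.0013, adjusted p = 0.53 with an estimated correlation). LGR5, the stem cell receptor, rose from 1.43 ± 0.767 to 3.05 ± 2.52 CPM (log2 fold change 1.09, SE 0.35, adjusted p = 0.006, 11 of 16), and was 0.62 with adjusted p = 0.12 in limma-voom.

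Genes that package dietary fat fell at 4 weeks: 15 of 22 fat absorption and chylomicron genes fell and 2 rose. Members had a median log2 fold change of −1.01 (camera adjusted p = 2.3e-06, adjusted p = 0.53 with an estimated correlation). DGAT2 (ENSSSCG00000034102, chromosome 9, 10032163 to 10066082, protein-coding), which completes triglycerides, went from 1330 ± 264 to 84.8 ± 64.0 CPM (log2 fold change −3.97, SE 0.29, adjusted p = 9.6e-19), and the chylomicron apolipoprotein APOA4 (ENSSSCG00000040689, chromosome 9, 44201587 to 44204072, protein-coding) from 35700 ± 11300 to 5040 ± 2180 CPM (−2.82, SE 0.19, adjusted p = 2.4e-20), in 16 of 16 piglets each. Of 25 genes of fatty acid oxidation and ketogenesis, 19 fell and 1 rose. As a group they had a median of −0.53 (camera adjusted p = 1.5e-05, adjusted p = 0.53 with an estimated correlation), and of −0.32 with library size alone. They included the peroxisomal genes PEX11A (201 ± 48.5 to 45.7 ± 16.0 CPM, log2 fold change −2.14, SE 0.17, adjusted p = 2.5e-17) and HSD17B4 (−1.19, SE 0.1, adjusted p = 1.5e-15). In the same fasted piglets, absorptive enterocyte markers averaged per pig were lower by 0.45 on the log2 scale (permutation adjusted p = 0.0023, and 0.03 with adjusted p = 0.84 by the median over markers). BEST4 enterocyte markers were higher by 0.76 (adjusted p = 0.011). CPT1A, the gate for mitochondrial fat oxidation, was at 325 ± 99.9 CPM in fed and 275 ± 59.2 CPM in fasted piglets (−0.24, SE 0.14, adjusted p = 0.12).

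Nuclear respiratory chain genes fell in 25 of 28 and rose in 0. The median of the group was −0.32 (camera adjusted p = 1.5e-05, adjusted p = 0.53 with an estimated correlation) and −0.09 with library size alone as the scaling. UQCRFS1 of complex III went from 200 ± 30.4 to 124 ± 15.5 CPM (log2 fold change −0.69, SE 0.08, adjusted p = 1.9e-11), and COX7B of complex IV fell by 0.65 on the log2 scale (SE 0.08, adjusted p = 1.2e-10). The 13 mitochondrially encoded genes held 5.651 ± 0.742% of the counts in fed and 3.292 ± 0.863% in fasted 4-week piglets. Of 17 genes for iron, calcium and zinc handling, 12 fell and 3 rose. Their median log2 fold change was −1.12 (camera adjusted p = 0.0015, adjusted p = 0.53 with an estimated correlation).

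Other large falls at 4 weeks were those of the scaffold gene HOMER2 (128 ± 48.8 to 4.52 ± 5.14 CPM, log2 fold change −4.83, SE 0.51, adjusted p = 1.4e-12), the ring finger gene RNF207 (−3.81, SE 0.28, adjusted p = 1.7e-18) and the small heat shock gene HSPB8 (−3.6, SE 0.28, adjusted p = 2.2e-17). CYP1A1, which oxidises foreign compounds, was at −3.93 (SE 1.0, adjusted p = 0.00052), but fed pig 15 held nearly all of the fed counts, and without that pig the value was −0.34 (SE 1.03, adjusted p = 0.79). Without pig 15 the fed mean was 0.23 ± 0.356 CPM.

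Smooth muscle markers fell in 9 of 10 and rose in 0 at 4 weeks. Members had a median log2 fold change of −1.56 (camera adjusted p = 6e-05, adjusted p = 0.53 with an estimated correlation). Examples were the contractile genes ACTG2 (96.8 ± 43.6 to 12.5 ± 10.6 CPM, log2 fold change −2.95, SE 0.29, adjusted p = 1.6e-13) and CNN1 (−2.39, SE 0.29, adjusted p = 1.5e-10). Fibroblast and stroma markers fell in 8 of 12 and rose in 0 (median −0.93, camera adjusted p = 0.003, adjusted p = 0.61 with an estimated correlation), and blood endothelium markers fell in 7 of 9 and rose in 0 (median −0.95, camera adjusted p = 0.003, adjusted p = 0.53 with an estimated correlation). With smooth muscle and B cell marker levels as covariates these medians were −0.09, 0.58 and 0.15. The smooth muscle value is near 0 by construction, since that list was adjusted for its own level. Averaged per pig, the smooth muscle markers were lower by 1.94 on the log2 scale in the same fasted piglets whose fat and mineral genes fell and whose cell cycle and interferon genes rose (permutation adjusted p = 4.6e-05, 16 of 16). Markers of enteric neurons and glia were lower by 0.73 (adjusted p = 4.6e-05) and enteroendocrine markers by 0.43 (adjusted p = 0.00022).

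Of the genes of digestion and absorption fixed in advance, the sucrase gene SI fell from 2760 ± 491 to 2050 ± 1030 CPM at 4 weeks (log2 fold change −0.43, SE 0.19, adjusted p = 0.038), a call lost with library size alone as the scaling (−0.27, adjusted p = 0.15). The mucin gene MUC2 rose by 0.36 (SE 0.15, adjusted p = 0.036), which was 0.28 with adjusted p = 0.27 under the marker covariates. The glucose transporter SLC5A1 was at 1760 ± 523 and 2130 ± 883 CPM (adjusted p = 0.14, and 0.42 with adjusted p = 0.0089 with library size alone), the peptide transporter SLC15A1 at 553 ± 156 and 575 ± 231 CPM (adjusted p = 0.76), and the gluconeogenic PCK1 at 909 ± 419 and 917 ± 759 CPM (adjusted p = 0.98). Adjusted over the list alone, 2 fatty acid oxidation genes rose, 10 smooth muscle and 9 blood endothelium markers fell and 13 mineral genes fell, and counts of the other called lists were unchanged.

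**Figure D2:**
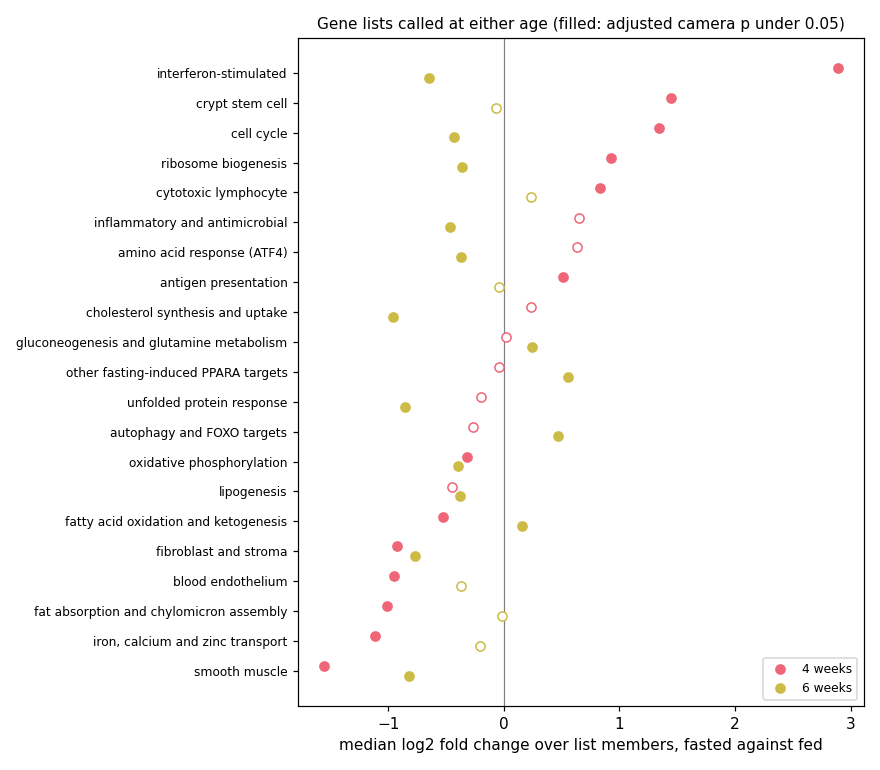
Median log2 fold change of fasted against fed piglets at 4 and at 6 weeks of age, for gene lists called at either age only. Filled points mark lists past an adjusted camera p of 0.05 at that age. The interferon list is at 2.89 at 4 weeks and at −0.65 at 6 weeks.

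The next comparison asked what 48 h of fasting changed in weaned 6-week piglets. Most genes of protein folding in the endoplasmic reticulum, cholesterol synthesis and the respiratory chain and most interferon-stimulated genes fell, and most autophagy genes rose. Some fatty acid synthesis and cell cycle genes fell and some gluconeogenesis, glutamine metabolism and fat oxidation genes rose, but most members of these lists did not pass or went the other way, and none of the list calls held with an estimated correlation. In all, 3197 genes rose and 2588 fell, with 280 and 266 of these at least 2-fold.

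Unfolded protein response genes fell in 18 of 18 at 6 weeks. As a group they had a median of −0.86 (camera adjusted p = 7e-19, adjusted p = 0.076 with an estimated correlation). The lumenal chaperones HSPA5 (1180 ± 362 to 374 ± 119 CPM, log2 fold change −1.66, SE 0.16, edgeR adjusted p = 3.4e-12) and HSP90B1 (1180 ± 257 to 469 ± 137 CPM, −1.33, SE 0.13, adjusted p = 7.1e-12) were below the fed median in 16 of 16 fasted piglets. Goblet cell markers averaged per pig were lower by 0.30 in the same fasted piglets (permutation adjusted p = 0.033), blood endothelium markers by 0.45 (adjusted p = 0.009) and enteric neuron and glia markers by 0.29 (adjusted p = 0.0045). By the median over markers the goblet cell difference was −0.73 and the enteric neuron and glia call was lost (−0.15, adjusted p = 0.26). Calls gained by that median were absorptive enterocytes (−0.33, adjusted p = 0.00064, against −0.11 and 0.22 by the mean), T cells (0.44, adjusted p = 0.0094) and macrophages and dendritic cells (−0.36, adjusted p = 0.006). Amino acid stress genes driven by ATF4 fell in 12 of 24 and rose in 3 (median −0.37, camera adjusted p = 0.0051, adjusted p = 0.31 with an estimated correlation).

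Cholesterol synthesis genes and some fatty acid synthesis genes fell at 6 weeks. Of 23 cholesterol synthesis genes, 20 fell and 0 rose. The median of the group was −0.96 (camera adjusted p = 3.2e-12, adjusted p = 0.31 with an estimated correlation). An example was NSDHL (61.5 ± 13.6 to 31.7 ± 7.45 CPM, log2 fold change −0.96, SE 0.12, adjusted p = 1e-08). Of 19 fatty acid synthesis genes, 9 fell and 2 rose (median −0.38, camera adjusted p = 0.00086, adjusted p = 0.074 with an estimated correlation), with a median of −0.20 under the marker covariates. The desaturase SCD went from 55.8 ± 38.3 to 6.75 ± 2.76 CPM (log2 fold change −3.04, SE 0.25, adjusted p = 1.2e-14) and the elongase ELOVL6 fell by 1.23 on the log2 scale (SE 0.14, adjusted p = 1.1e-09), in 16 of 16 piglets each. At 4 weeks 10 of 19 members fell and 5 rose (median −0.45, camera adjusted p = 0.097, and a median of −0.17 under the covariates). There ELOVL6 went from 270 ± 84.7 to 35.2 ± 11.8 CPM (−2.94, SE 0.15, adjusted p = 6.7e-25) and SCD was at −1.37 (SE 0.24, adjusted p = 1.9e-06).

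Several fuel genes rose at 6 weeks. A large rise was that of PDK4 (ENSSSCG00000015334, chromosome 9, 75246956 to 75260134, protein-coding), which blocks entry of pyruvate into the mitochondrial cycle, from 6.86 ± 2.72 to 73.8 ± 31.3 CPM (log2 fold change 3.43, SE 0.24, adjusted p = 1.5e-17). PCK1 (ENSSSCG00000007507, chromosome 17, 57930507 to 57936523, protein-coding) rose from 166 ± 149 to 1780 ± 739 CPM (3.42, SE 0.38, adjusted p = 3.1e-10) and CPT1A from 66.9 ± 18.4 to 123 ± 36.7 CPM (0.88, SE 0.14, adjusted p = 8.7e-07), all in 16 of 16 piglets. Autophagy and FOXO genes rose in 18 of 24 and fell in 1. Their median log2 fold change was 0.47 (camera adjusted p = 9.5e-06, adjusted p = 0.31 with an estimated correlation). Examples were the ubiquitin ligase FBXO32 (1.24, SE 0.17, adjusted p = 2.5e-08) and the insulin receptor INSR (1.27, SE 0.19, adjusted p = 1.8e-07). PPARA target genes rose in 8 of 15 and fell in 2 (median 0.55, camera adjusted p = 0.038, adjusted p = 0.31 with an estimated correlation). Gluconeogenesis and glutamine metabolism genes rose in 9 of 22 and fell in 4 (median 0.24, camera adjusted p = 0.046, adjusted p = 0.61 with an estimated correlation). Fatty acid oxidation genes rose in 10 of 25 and fell in 2 (median 0.16, camera adjusted p = 0.046, adjusted p = 0.64 with an estimated correlation). Under the marker covariates the medians of these lists were 0.13 and 0.09.

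Respiratory chain genes fell in 24 of 28 and rose in 0 at 6 weeks. Members had a median log2 fold change of −0.40 (camera adjusted p = 1.7e-13, adjusted p = 0.31 with an estimated correlation). NDUFS1 of complex I fell by 0.49 on the log2 scale (101 ± 12.8 to 71.7 ± 13.5 CPM, SE 0.07, adjusted p = 2.3e-07) and the ATP synthase subunit ATP5F1A by 0.6 (SE 0.09, adjusted p = 3e-07). Mitochondrially encoded genes held 5.653 ± 1.588% of the counts in fed and 5.164 ± 1.394% in fasted piglets.

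Interferon-stimulated genes fell in 18 of 29 and rose in 0 at 6 weeks (median −0.65, camera adjusted p = 2.1e-06, adjusted p = 0.61 with an estimated correlation). Examples were the antiviral OAS1 (1040 ± 446 to 493 ± 334 CPM, log2 fold change −1.08, SE 0.23, adjusted p = 9.7e-05) and RSAD2 (−1.53, SE 0.35, adjusted p = 0.00033). The fall was not uniform. The mean log2 CPM of the list ranged from 5.99 to 8.47 in fasted and from 5.94 to 8.57 in fed 6-week piglets. Below the whole fed range lay 3 of 16 fasted piglets for OAS1 and 8 of 16 for RSAD2. Inflammatory and antimicrobial genes fell in 6 of 18 and rose in 1 (median −0.47, camera adjusted p = 0.024, adjusted p = 0.61 with an estimated correlation), with a median of −0.12 under the marker covariates. Cell cycle genes fell in 11 of 29 and rose in 0 (median −0.43, camera adjusted p = 0.0003, adjusted p = 0.65 with an estimated correlation). Examples were the replication genes CDC6 (−0.69, SE 0.19, adjusted p = 0.0027) and MCM6 (−0.44, SE 0.12, adjusted p = 0.003). Ribosome assembly genes fell in 14 of 26 and rose in 0 (median −0.36, camera adjusted p = 0.00086, adjusted p = 0.64 with an estimated correlation). Examples were NOP14 (−0.8, SE 0.21, adjusted p = 0.0014) and NOLC1 (−0.62, SE 0.16, adjusted p = 0.0016).

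Single genes with large changes at 6 weeks included the bile acid transporter SLC10A2 (ENSSSCG00000026317, chromosome 11, 71328801 to 71348779, protein-coding), which went from 37.1 ± 28.8 to 1.27 ± 1.48 CPM (log2 fold change −4.85, SE 0.5, adjusted p = 4.3e-11). The hyaluronan synthase HAS2 (−3.65, SE 0.41, adjusted p = 3e-10), the collagen gene COL8A1 (−2.46, SE 0.26, adjusted p = 5.8e-11) and the peroxide-reducing GPX2 (−2.43, SE 0.42, adjusted p = 5.7e-06) were below the fed median in 16 of 16 fasted piglets. Below the whole fed range lay 4, 10 and 13 fasted piglets in that order. The phosphatase PTPRR rose by 2.81 (SE 0.32, adjusted p = 3.1e-10). The metallothionein MT1X (3.12, SE 0.38, adjusted p = 2.2e-09) and the peptidase gene FOLH1B (3.01, SE 0.47, adjusted p = 5.9e-07) also rose, but belong to families of similar copies, which leaves their levels uncertain.

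APOA4 fell from 6740 ± 2870 to 2450 ± 529 CPM at 6 weeks (log2 fold change −1.46, SE 0.18, adjusted p = 2.2e-09) and MUC2 by 0.43 on the log2 scale (SE 0.15, adjusted p = 0.019). The absorptive genes SI (4900 ± 804 and 5190 ± 1640 CPM, adjusted p = 0.74), SLC5A1 (3540 ± 676 and 3360 ± 866 CPM, adjusted p = 0.73) and SLC15A1 (1130 ± 247 and 1070 ± 258 CPM, adjusted p = 0.7) did not pass, nor did LGR5 (adjusted p = 0.39). Smooth muscle markers fell in 7 of 10 and rose in 0 (median −0.82, camera adjusted p = 0.0021, adjusted p = 0.61 with an estimated correlation), with a median of 0.08 under the marker covariates. That last value is near 0 by construction, since the covariates hold the level of this same list. Fibroblast markers fell in 9 of 12 and rose in 0 (median −0.77, camera adjusted p = 0.004, adjusted p = 0.64 with an estimated correlation), with a median of 0.13 under the covariates. Averaged per pig, smooth muscle markers were lower by 0.88 on the log2 scale in the fasted piglets whose chaperone and lipid synthesis genes fell (permutation adjusted p = 0.00015, 16 of 16). Adjusted over the list alone, 21 cholesterol, 21 interferon, 17 ribosome assembly, 9 cell cycle genes and 8 smooth muscle markers fell, and the counts of the other called lists were unchanged.

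**Figure D3:**
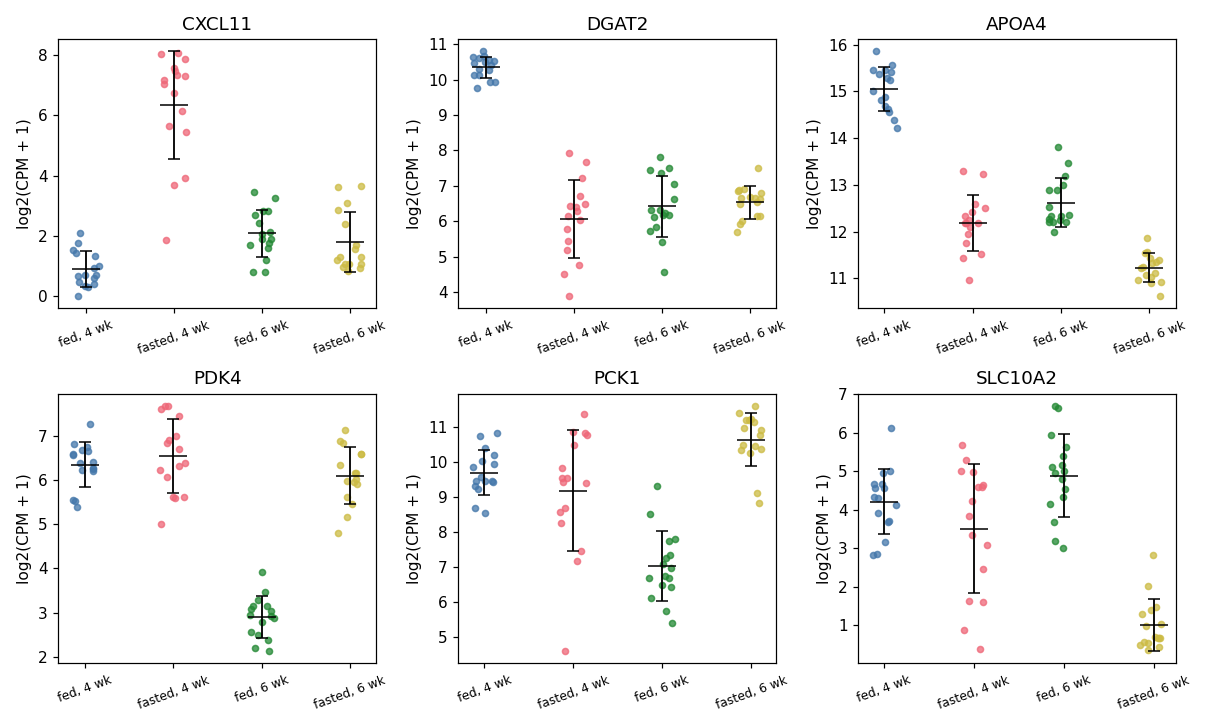
Levels of CXCL11, DGAT2, APOA4, PDK4, PCK1 and SLC10A2 as log2(CPM + 1), with each point a pig and 16 pigs per group. PDK4 is at 84.9 ± 28.4 CPM in fed 4-week and 6.86 ± 2.72 CPM in fed 6-week piglets.

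The third comparison asked whether the response to fasting differed between the 2 ages, by the difference of the log2 fold changes (6 weeks minus 4 weeks). Fasted 4-week piglets were also separated from the sow and moved to another pen, so a difference cannot be put down to age alone. Most antiviral, proliferative and ribosome assembly genes rose with fasting at 4 weeks, and part of them fell at 6 weeks. Most fat absorption and fat oxidation genes fell at 4 weeks, and at 6 weeks these lists had medians of −0.02 and 0.16. No list difference held with an estimated correlation. The difference was above 0 for 3817 genes and below 0 for 3739, and 2213 and 5515 with library size alone. The median gene was at −0.22 with library size alone, against 0.02 with TMM. Across the tested genes, which are not independent replicates, the fasting responses at the 2 ages had a Pearson r of 0.035 and a Spearman rho of 0.052. Of the genes that passed at both ages, 1120 rose at both (1084 if independent), 998 fell at both (762), 860 rose at 4 weeks and fell at 6 weeks (878), and 746 fell at 4 weeks and rose at 6 weeks (941).

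Of 29 interferon-stimulated genes, 28 had a lower response at 6 weeks and 0 a higher one (median difference −3.45, camera adjusted p = 9.6e-26, adjusted p = 0.38 with an estimated correlation). OASL differed by −7.73 (SE 0.69, adjusted p = 2.5e-14), CXCL11 by −7.08 (SE 0.68, adjusted p = 2.3e-13), NUPR1 by −6.56 (SE 0.60, adjusted p = 5.6e-14) and the antiviral MX2 by −6.01 (SE 0.52, adjusted p = 9.3e-15). IFIT2 differed by −7.10 (SE 0.85, adjusted p = 2.3e-10), and by −7.94 without fasted 6-week pig 45. Antigen presentation was lower in 7 of 13 and higher in 1 (median −0.76, camera adjusted p = 0.00046, adjusted p = 0.55 with an estimated correlation). Inflammatory and antimicrobial genes were lower in 12 of 18 and higher in 1 (median −1.20, camera adjusted p = 0.0021, adjusted p = 0.55 with an estimated correlation). Plasma cell markers were lower in 5 of 9 and higher in 0 (median −1.37, camera adjusted p = 0.035, adjusted p = 0.55 with an estimated correlation).

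Cell cycle genes had a lower response at 6 weeks in 29 of 29 (median −1.80, camera adjusted p = 2.2e-10, adjusted p = 0.55 with an estimated correlation). Ribosome assembly genes did so in 25 of 26, with 0 higher (median −1.41, camera adjusted p = 4.5e-10, adjusted p = 0.55 with an estimated correlation). Crypt markers were lower in 13 of 17 and higher in 1 (median −1.53, camera adjusted p = 0.00065, adjusted p = 0.55 with an estimated correlation). Cholesterol synthesis was lower in 19 of 23 and higher in 2 (median −0.96, camera adjusted p = 8.8e-05, adjusted p = 0.55 with an estimated correlation). ATF4 genes were lower in 14 of 24 and higher in 3 (median −0.83, camera adjusted p = 0.0021, adjusted p = 0.55 with an estimated correlation). Unfolded protein response genes were lower in 11 of 18 and higher in 0 (median −0.71, camera adjusted p = 0.00057, adjusted p = 0.57 with an estimated correlation).

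Fat absorption genes had a higher response at 6 weeks in 19 of 22 and a lower one in 1 (median 0.96, camera adjusted p = 4.2e-06, adjusted p = 0.55 with an estimated correlation). DGAT2 differed by 3.93 (SE 0.37, adjusted p = 2e-13), with 99.0 ± 57.8 CPM in fed and 95.9 ± 31.1 CPM in fasted 6-week piglets, and APOA4 by 1.36 (SE 0.25, adjusted p = 4.3e-06). Fatty acid oxidation was higher in 19 of 25 and lower in 0 (median 0.59, camera adjusted p = 7.9e-07, adjusted p = 0.55 with an estimated correlation), with a median of 0.36 with library size alone. CPT1A was at 1.12 (SE 0.20, adjusted p = 2.1e-06). Autophagy genes were higher in 14 of 24 and lower in 1 (median 0.57, camera adjusted p = 0.00019, adjusted p = 0.55 with an estimated correlation), with a median of 0.34 with library size alone. PCK1 differed by 3.41 (SE 0.51, adjusted p = 7.6e-08). HOMER2 (4.89, SE 0.67, adjusted p = 8.9e-09), the F-box gene FBXL16 (4.31, SE 0.31, adjusted p = 1.6e-17) and the creatine synthesis gene GATM (3.75, SE 0.34, adjusted p = 4.4e-14) were among the largest values, as was CYP1A1, which was at 6.66 (SE 1.21, adjusted p = 4.7e-06), at 3.07 (adjusted p = 0.025) without fed 4-week pig 15 and at 3.00 (adjusted p = 0.32) in limma-voom. MUC2 differed by −0.79 (SE 0.22, adjusted p = 0.0016). Adjusted over the list alone, 20 fatty acid oxidation genes and 4 ATF4 genes were higher and 13 inflammatory genes and 6 plasma cell markers lower, with no change for the other called lists.

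The fourth comparison asked how fed piglets differed between 6 weeks, after weaning, and 4 weeks, on sow's milk. Most interferon-stimulated, cell cycle, goblet cell, T cell and cytotoxic lymphocyte genes were higher in fed 6-week piglets, and most fat-handling and enteroendocrine genes were lower. None of these list calls held when the correlation within lists was estimated. There were 4480 genes higher and 4548 lower at 6 weeks, 1335 and 990 of them at least 2-fold. With library size alone 6404 were higher and 2719 lower, and the median gene was at 0.2, against −0.01 with TMM.

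Interferon-stimulated genes were higher at 6 weeks in 28 of 29 and lower in 0 (median 1.79, camera adjusted p = 4e-11, adjusted p = 0.37 with an estimated correlation). OASL was at 5.82 (SE 0.54, adjusted p = 1.4e-14) and MX2 at 4.17 (25.9 ± 9.46 to 465 ± 300 CPM, SE 0.39, adjusted p = 1.8e-14). Cell cycle genes were higher in 28 of 29 and lower in 0 (median 1.65, camera adjusted p = 6.3e-10, adjusted p = 0.44 with an estimated correlation). CENPF was at 2.10 (SE 0.2, adjusted p = 5e-14) and CDK1 at 1.96 (SE 0.2, adjusted p = 9e-13). Ribosome assembly genes were higher in 24 of 26 and lower in 1 (median 0.92, camera adjusted p = 5.4e-07, adjusted p = 0.49 with an estimated correlation). Examples were UTP20 (1.5, SE 0.19, adjusted p = 3.4e-10) and NPM1 (0.99, SE 0.12, adjusted p = 8e-11). Crypt markers were higher in 12 of 17 and lower in 0 (median 0.94, camera adjusted p = 0.0028, adjusted p = 0.54 with an estimated correlation), and LGR5 did not pass (−0.62, SE 0.37, adjusted p = 0.14). Cholesterol synthesis was higher in 16 of 23 and lower in 1 (median 0.76, camera adjusted p = 0.00015, adjusted p = 0.54 with an estimated correlation).

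T cell, cytotoxic lymphocyte, plasma cell and goblet cell markers were higher in fed 6-week piglets, and B cell and follicle markers did not pass (difference per pig 0.08, permutation adjusted p = 0.78). T cell markers were higher in 10 of 11 and lower in 0 (median 1.06, camera adjusted p = 0.0001, adjusted p = 0.37 with an estimated correlation). Examples were the co-receptor genes CD8A (11.7 ± 5.88 to 54.8 ± 21.2 CPM, log2 fold change 2.23, SE 0.2, adjusted p = 9.4e-15) and CD8B (2.73, SE 0.23, adjusted p = 4e-16). Cytotoxic markers were higher in 8 of 10 and lower in 0 (median 1.59, camera adjusted p = 0.00014, adjusted p = 0.37 with an estimated correlation). Plasma cell markers were higher in 8 of 9 and lower in 0 (median 1.12, camera adjusted p = 0.0034, adjusted p = 0.37 with an estimated correlation). Inflammatory and antimicrobial genes were higher in 11 of 18 and lower in 1 (median 0.61, camera adjusted p = 0.0036, adjusted p = 0.37 with an estimated correlation). Antigen presentation was higher in 5 of 13 and lower in 0 (median 0.10, camera adjusted p = 0.01, adjusted p = 0.51 with an estimated correlation), with a median of 0.32 with library size alone and 0.30 under the marker covariates. Goblet cell markers were higher in 9 of 10 and lower in 0 (median 1.24, camera adjusted p = 7.3e-05, adjusted p = 0.37 with an estimated correlation). The secretory regulator SPDEF was at 1.58 (SE 0.13, adjusted p = 1.6e-16) and MUC2 at 1.58 (232 ± 61.0 to 695 ± 230 CPM, SE 0.16, adjusted p = 1.4e-13). Averaged per pig, T cell markers were higher by 1.16, cytotoxic by 1.38, plasma cell by 1.64 and goblet cell markers by 1.07, and smooth muscle markers lower by 0.61 (permutation adjusted p = 4.6e-05 for the first 4 and 0.0069 for smooth muscle). Macrophage and dendritic cell markers were higher by 0.80 and tuft cell markers lower by 0.57 (adjusted p = 4.6e-05 each), and blood endothelium markers were lower by 0.57 (adjusted p = 0.0024) and lymphatic endothelium markers by 0.49 (adjusted p = 0.00081).

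Fat absorption genes were lower at 6 weeks in 18 of 22 and higher in 2 (median −1.15, camera adjusted p = 5.4e-07, adjusted p = 0.37 with an estimated correlation). APOC3 went from 15500 ± 3900 to 1370 ± 675 CPM (log2 fold change −3.5, SE 0.25, adjusted p = 4.9e-19), APOA4 was at −2.40 (SE 0.18, adjusted p = 5.8e-18) and the cholesterol exporter ABCA1 at −2.81 (SE 0.19, adjusted p = 5.8e-20). Absorptive enterocyte markers averaged per pig were lower by 0.21 (permutation adjusted p = 0.0069) but at 0.40 by the median over markers (adjusted p = 0.00012), and BEST4 enterocyte markers were higher by 0.95 (adjusted p = 0.00022). Fatty acid oxidation was lower in 18 of 25 and higher in 3 (median −0.81, camera adjusted p = 3.2e-06, adjusted p = 0.37 with an estimated correlation). CPT1A was at −2.28 (SE 0.14, adjusted p = 2.6e-21) and PEX11A at −2.17 (SE 0.17, adjusted p = 1.2e-17). PPARA targets were lower in 9 of 15 and higher in 3 (median −0.91, camera adjusted p = 0.034, adjusted p = 0.37 with an estimated correlation). Autophagy genes were lower in 18 of 24 and higher in 1 (median −0.69, camera adjusted p = 0.00016, adjusted p = 0.39 with an estimated correlation). Mineral genes were lower in 10 of 17 and higher in 2 (median −0.72, camera adjusted p = 0.013, adjusted p = 0.37 with an estimated correlation). Enteroendocrine markers were lower in 15 of 16 and higher in 1 (median −1.04, camera adjusted p = 7.8e-07, adjusted p = 0.28 with an estimated correlation). The ghrelin gene GHRL was at −3.21 (SE 0.26, adjusted p = 4.4e-17) and the granule gene CHGA at −1.51 (SE 0.13, adjusted p = 3.5e-16).

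The catecholamine synthesis gene TH (ENSSSCG00000039767, chromosome 2, 1499628 to 1506180, protein-coding) had a large fall, from 144 ± 52.7 to 2.0 ± 1.03 CPM (log2 fold change −6.17, SE 0.31, adjusted p = 7.9e-26), and so did FOLH1B (−5.58, SE 0.52), HOMER2 (−4.88, SE 0.51), the growth factor PGF (−4.78, SE 0.29) and the sugar transporter SLC2A8 (−4.29, SE 0.32). CYP1A1 (ENSSSCG00000001906, chromosome 7, 58802887 to 58809155, protein-coding) was higher by 6.78 (SE 0.86, adjusted p = 5.3e-10), and by 10.36 without fed 4-week pig 15. The other large rises were those of the ubiquitin ligase NEURL3 (5.07, SE 0.47), the chemokine CCL26 (5.02, SE 0.4) and the carbonic anhydrase CA12 (4.77, SE 0.36). SI (0.83, SE 0.19, adjusted p = 0.00011), SLC5A1 (1.01, SE 0.16, adjusted p = 3e-07) and SLC15A1 (1.03, SE 0.15, adjusted p = 1.9e-08) were higher and PCK1 lower (−2.45, SE 0.37, adjusted p = 4.5e-08) at 6 weeks. Adjusted over the list alone, 19 fat absorption and 19 fatty acid oxidation genes were lower, with no change for the other called lists.

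**Figure D4:**
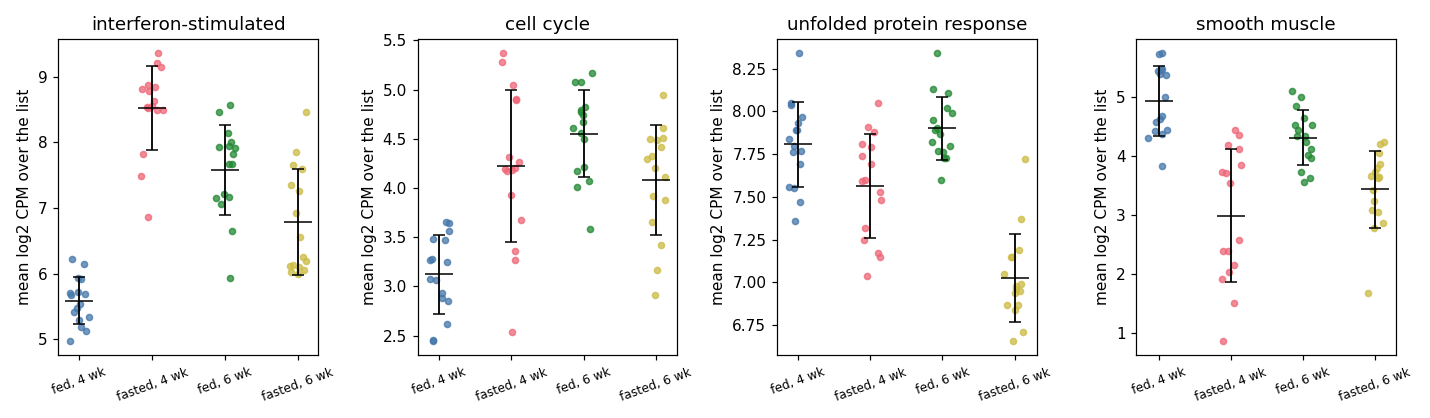
Mean log2 CPM of 4 gene lists per pig in the 4 groups, with each point a pig and bars for the mean ± SD of 16 pigs. The interferon list is at 5.59 ± 0.36 in fed 4-week, 8.53 ± 0.64 in fasted 4-week, 7.58 ± 0.68 in fed 6-week and 6.78 ± 0.81 in fasted 6-week piglets.

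The last comparison asked how fasted piglets differed between 6 and 4 weeks. Most interferon-stimulated, protein-folding and enteroendocrine genes were lower in fasted 6-week piglets. Most T cell and goblet cell markers were higher, as were part of the nutrient transporter and foreign-compound metabolism genes. As in the other comparisons, no list call held with an estimated correlation. There were 2770 genes higher and 3266 lower, with 387 and 626 of these at least 2-fold.

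Interferon-stimulated genes were lower in 27 of 29 and higher in 0 (median −1.62, camera adjusted p = 1.7e-19, adjusted p = 0.18 with an estimated correlation). Examples were CXCL10 (1120 ± 639 to 94.7 ± 96.8 CPM, log2 fold change −3.56, SE 0.39, adjusted p = 5.8e-11) and the RNA sensor IFIH1 (−1.26, SE 0.16, adjusted p = 1.3e-09). CXCL11 was at −5.18 (SE 0.48, adjusted p = 3.1e-13) and NUPR1 at −4.25 (SE 0.42, adjusted p = 2.4e-12). Antigen presentation was lower in 7 of 13 and higher in 1 (median −0.35, camera adjusted p = 0.033, adjusted p = 0.7 with an estimated correlation). Unfolded protein response genes were lower in 15 of 18 and higher in 0 (median −0.68, camera adjusted p = 5.5e-07, adjusted p = 0.3 with an estimated correlation). HSPA5 was at −1.02 (SE 0.16, adjusted p = 2.8e-07) and the calcium-binding chaperone CALR at −0.74 (SE 0.1, adjusted p = 3.3e-08). ATF4 genes were lower in 13 of 24 and higher in 2 (median −0.57, camera adjusted p = 0.00063, adjusted p = 0.18 with an estimated correlation). The stress-response factor CEBPB was at −1.75 (SE 0.17, adjusted p = 1e-12). Ribosome assembly genes were lower in 16 of 26 and higher in 0 (median −0.39, camera adjusted p = 0.0049, adjusted p = 0.83 with an estimated correlation). Tight junction genes were lower in 10 of 17 and higher in 1 (median −0.38, camera adjusted p = 0.004, adjusted p = 0.21 with an estimated correlation).

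T cell markers were higher in 8 of 11 and lower in 0 (median 0.74, camera adjusted p = 1.3e-05, adjusted p = 0.23 with an estimated correlation). CD8B was at 2.08 (SE 0.22, adjusted p = 1.7e-11) and the receptor adaptor TRAT1 at 1.18 (SE 0.15, adjusted p = 2.6e-09). Cytotoxic markers were higher in 8 of 10 and lower in 1 (median 0.90, camera adjusted p = 0.00031, adjusted p = 0.3 with an estimated correlation). The granzyme gene GZMA was paired with 2 gene IDs, at 1.85 each (SE 0.21 and 0.24), and such similar copies leave its level uncertain. Goblet markers were higher in 8 of 10 and lower in 0 (median 0.74, camera adjusted p = 1.8e-05, adjusted p = 0.18 with an estimated correlation). Examples were the mucus-processing CLCA1 (333 ± 155 to 1050 ± 523 CPM, log2 fold change 1.66, SE 0.22, adjusted p = 6.5e-09), BCAS1 (1.1, SE 0.12, adjusted p = 1.4e-11) and MUC2 (0.80, SE 0.15, adjusted p = 2.2e-05). Enteroendocrine markers were lower in 14 of 16 and higher in 1 (median −0.75, camera adjusted p = 1.3e-06, adjusted p = 0.18 with an estimated correlation). GHRL was at −2.58 (SE 0.27, adjusted p = 1e-11) and CHGB at −1.49 (SE 0.17, adjusted p = 3.1e-10). Tuft cell markers were lower in 4 of 7 and higher in 0 (median −0.87, camera adjusted p = 0.0071, adjusted p = 0.18 with an estimated correlation).

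Sugar, peptide and amino acid transport genes were higher in 13 of 22 and lower in 3 (median 0.55, camera adjusted p = 0.00056, adjusted p = 0.43 with an estimated correlation). The fructose transporter SLC2A5 went from 67.0 ± 34.0 to 199 ± 54.4 CPM (log2 fold change 1.57, SE 0.19, adjusted p = 5.2e-10), the proline transporter SLC6A20 was at 1.62 (SE 0.18, adjusted p = 4.2e-11), SLC15A1 at 0.90 (SE 0.15, adjusted p = 1.5e-06) and SLC5A1 at 0.66 (SE 0.16, adjusted p = 0.00078). Brush border enzymes were higher in 6 of 14 and lower in 1 (median 0.43, camera adjusted p = 0.0049, adjusted p = 0.62 with an estimated correlation), with SI at 1.34 (SE 0.19, adjusted p = 4.1e-08). Gluconeogenesis and glutamine metabolism genes were higher in 8 of 22 and lower in 0 (median 0.25, camera adjusted p = 0.0049, adjusted p = 0.34 with an estimated correlation). PCK1 was at 0.96 (SE 0.35, adjusted p = 0.023). Suckling-stage enterocyte genes were lower in 7 of 16 and higher in 2 (median −0.28, camera adjusted p = 0.026, adjusted p = 0.43 with an estimated correlation), and bile acid genes lower in 6 of 10 and higher in 0 (median −0.67, camera adjusted p = 0.015, adjusted p = 0.18 with an estimated correlation). APOA4 was at −1.04 (SE 0.18, adjusted p = 2e-06), CPT1A at −1.16 (SE 0.14, adjusted p = 7.4e-10) and LGR5 at −1.31 (SE 0.36, adjusted p = 0.0022).

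Foreign-compound metabolism genes were higher in 8 of 13 and lower in 1 (median 0.53, camera adjusted p = 0.0015, adjusted p = 0.18 with an estimated correlation). CYP1A1 went from 0.185 ± 0.201 to 2050 ± 1960 CPM (log2 fold change 13.43, SE 1.16, adjusted p = 2.3e-14), with 0 to 14 counts per fasted 4-week and 416 to 112544 per fasted 6-week pig. The other large rises were those of the cytidine deaminase CDA (3.68, SE 0.29), the brush border phospholipase PLB1 (3.61, SE 0.43), the homeobox gene DLX4 (3.26, SE 0.28) and FAM151A (2.94, SE 0.56). Other large falls were in the cytoskeletal DTNA (−4.24, SE 0.33, and −4.85 without fasted 6-week pig 41), TH (−3.88, SE 0.28) and the matrix glycoprotein SPP1 (−3.77, SE 0.78). Averaged per pig, T cell markers were higher by 0.87, cytotoxic markers by 0.90 and goblet markers by 0.75, with enteroendocrine markers lower by 0.85 and tuft cell markers by 0.57 (permutation adjusted p = 4.6e-05 each). By the median over markers the goblet difference was smaller, at 0.41 (adjusted p = 0.016), and the T cell and cytotoxic ones were larger, at 1.23 and 1.24. B cell and follicle markers were lower by 0.62 (adjusted p = 0.011). Enteric neuron and glia markers were higher by 0.23 (adjusted p = 0.014), a call lost by the median over markers (0.12, adjusted p = 0.43), and smooth muscle markers were at 0.45 (adjusted p = 0.23). Adjusted over the list alone, 28 interferon and 17 ribosome assembly genes were lower, 3 ATF4 genes were higher, and tuft cell markers were lower in 5 and higher in 1, with no change for the other called lists.

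All tests of genes were edgeR quasi-likelihood tests on 64 pigs with 16 per group, and list tests used camera with a preset correlation of 0.01. No called list passed with an estimated correlation, so the list calls rest on the preset. Lists called in no comparison included those of the circadian clock (smallest camera adjusted p = 0.11), glucocorticoid-responsive genes (0.12), vitamin A metabolism (0.068), macrophages and dendritic cells (0.054), B cells and follicles (0.14) and absorptive enterocytes (0.48). Libraries of a group shared age, diet and place, and no litter, pen or day of sampling was given in the labels.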

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

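The tests of single pigs against the fed maximum and of the 6-week interferon median, and the plasma cell and T cell marker tests, were chosen only after the result was seen. Every value in the next paragraphs was singled out because the fasting response differed between the ages by the interaction test in edgeR. For lists the test was camera with a preset correlation, where no list call held with an estimated correlation. Each value is the log2 response at 6 weeks minus that at 4 weeks. At 4 weeks fasting came with separation from the sow and a change of pen, so these differences cannot be put down to age alone.

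Among antiviral, antigen presentation and related genes, the differences were −7.73 for OASL, −7.10 for IFIT2, −7.08 for CXCL11, −6.01 for MX2, −5.62 for RSAD2, −2.63 for OAS1, −2.17 for TAP1, −2.13 for IFI44L and −1.72 for PSMB8, with −5.59 for CCR7 and −6.56 for NUPR1. The list medians were −3.45 for interferon-stimulated genes, −0.76 for antigen presentation, −1.20 for inflammatory genes and −1.37 for plasma cell markers, with 0 lists called when the correlation was estimated. Cell cycle and ribosome assembly genes were at −2.58 for CENPF, −2.25 for CDK1, −1.74 for MYC, −1.48 for NOP14, −1.46 for CDC6, −1.43 for NOLC1, −1.0 for NPM1 and −0.53 for MCM6, with medians of −1.80 for the cell cycle, −1.41 for ribosome assembly and −1.53 for crypt markers.

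Lower responses at 6 weeks were also found for SLC10A2 (−4.57), GPX2 (−3.84), HAS2 (−3.29), COL8A1 (−2.34) and MUC2 (−0.79). Among lipid synthesis and folding genes they were −1.67 for SCD, −0.69 for NSDHL, −1.42 for HSPA5 and −1.35 for HSP90B1, with medians of −0.96 for cholesterol synthesis, −0.71 for the unfolded protein response and −0.83 for ATF4 genes. Respiratory chain genes ATP5F1A and COX7B were at −0.35 and 0.35.

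Higher responses at 6 weeks were 3.93 for DGAT2, 3.41 for PCK1, 3.09 for PDK4, 2.22 for PEX11A, 1.71 for ELOVL6, 1.36 for APOA4, 1.29 for HSD17B4 and 1.12 for CPT1A, with medians of 0.96 for fat absorption and 0.59 for fatty acid oxidation. Other values were 6.66 for CYP1A1 (resting in part on fed 4-week pig 15), 4.89 for HOMER2, 4.31 for FBXL16, 3.75 for GATM, 3.21 for FOLH1B, 3.16 for HSPB8, 2.88 for PTPRR, 2.62 for RNF207, 2.23 for INSR and 0.61 for FBXO32, with 0.57 for the autophagy list. The contractile genes ACTG2 and CNN1 were at 1.42 and 1.18.

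The first pattern weighed was the rise of interferon-stimulated genes in fasted 4-week piglets. A few libraries did not carry it, since 16 of 16 fasted pigs lay above the highest fed pig (lowest fasted 6.87, highest fed 6.22 in mean log2 CPM), and scaling did not, with a median of 3.07 with library size alone. More leukocytes in the scraping were argued against by a median of 2.91 with T cell and macrophage marker levels as covariates, where the mean list level per pig differed by 2.74 (SE 0.28), against 2.94 (SE 0.23) without them. With fasting at 6 weeks the list had a median of −0.65, so absence of feed did not raise it at that age. Fed 6-week piglets already had a list mean of 7.58 ± 0.68, against 5.59 ± 0.36 in fed 4-week piglets. They also differed in age, diet and housing, so the 6-week median cannot decide about absence of feed at 4 weeks. Absence of feed, milk withdrawal, separation from the sow and the change of pen stay open.

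The second pattern was the fall of smooth muscle and stromal markers in fasted piglets. At 4 weeks plasma cell markers were at a median of 0.79, with 6 of 9 higher, so not all non-epithelial markers fell. Marker levels of other leukocytes rose too, by 0.55 for T cells and 0.86 for macrophages and dendritic cells. Such a rise could hide a smaller share of all non-epithelial tissue, so the plasma cell markers cannot decide about it. At 6 weeks T cell markers were at 0.33 with 5 higher, but 3 plasma cell markers were lower. Less of all non-epithelial tissue cannot be told apart there from a fall in stroma alone. With smooth muscle and B cell marker levels as covariates 73.4% of the calls at 4 weeks and 75% at 6 weeks were kept in the same direction, which fell between the bounds set beforehand and left open how far the stromal share moved other genes. Depth of scraping and a change in the mucosa itself stay open.

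The third pattern was that the 4-week fasting response resembled the age difference among fed piglets. In both, 3242 genes were higher (1519 if independent) and 2934 lower (1339), though shared controls raise such overlaps by themselves. Pearson r across genes was 0.718, where simulated unchanged groups that share their controls gave 0.507 (SD 0.011). Sharing alone gives such an r without any change, so the covariance was compared too, at 0.5049 in the data and 0.015 in the simulation. Shared fed 4-week libraries were argued against as the whole cause by an r of 0.688 (SD 0.021 over 100 splits) with those pigs split between the comparisons. The stromal and follicle share was argued against by 0.739 (SD 0.012 over splits) with marker covariates as well. Splitting could not remove what all fed 4-week pigs had in common. Between the fasting responses at 4 and 6 weeks r was 0.035 (bootstrap SD 0.075). The 6-week piglets were weaned and also differed in age, diet and housing. This r therefore cannot decide about absence of feed at 4 weeks, which stays open. Loss of sow's milk is shared by both comparisons and stays open with separation from the sow, untested.

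A chance assignment of the pigs was argued against for the counts of the fasting and the age comparisons. Of 100 splits of the pigs only 1, the real one, reached 8909 (highest other 4670) for fasting at 4 weeks, 5785 (37) at 6 weeks, 9028 (2633) for age in fed and 6036 (2896) for age in fasted piglets. For the difference between ages the counts were 7556 and 3, but those splits shuffled age within fed and within fasted pigs. This removed the age effect as well, so it cannot test the difference alone. No split could address litter, pen or batch.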

How the results depend on the processing

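Fits without fasted 4-week pigs 1, 28 and 32 and without fed 4-week pig 15 were chosen after seeing the data. So were those without fasted 6-week pig 45 for IFIT2 and pig 41 for DTNA, which are not among the settings counted next. The other alternatives were planned. Of 1393 values of 146 results named by the rule under 11 settings, 1345 kept their direction and side of the threshold, 35 were weaker, 1 stronger and 12 reversed, with 24 of the weaker under the 1.5-fold test. The cause was not tested except where the construction shows it, as for the stricter 1.5-fold test. That test called 1564 genes higher and 1218 lower for fasting at 4 weeks, 172 and 163 at 6 weeks, 1111 and 1562 for their difference, 1523 and 1278 for age in fed and 320 and 582 for age in fasted piglets. Library size alone gave 2518 lower for fasting at 4 weeks, 2213 higher for the difference and 2719 lower for age in fed piglets. Without the filter 24 lists were called for fasting at 4 weeks and 21 for the difference. With an estimated correlation camera called 0 lists in each comparison, with 2, 5, 3, 4 and 9 at an unadjusted p under 0.05, in the order above, where fry called 34 for fasting at 4 weeks, 23 at 6 weeks, 27 for the difference, 34 for age in fed and 21 for age in fasted piglets.

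Reversed values were all of uncalled genes or levels, except the enterocyte levels. PCK1 for fasting at 4 weeks was at 0.00 under DESeq2 size factors and under DESeq2, −0.03 without the filter, −0.40 in limma-voom, −0.31 with surrogate variables, −0.30 with marker covariates and −0.16 without the 3 pigs. SLC15A1 at 4 weeks was at −0.06 with surrogate variables, −0.27 with marker covariates and −0.06 without the 3 pigs, SLC5A1 at −0.01 and SI at 6 weeks at 0.00 with marker covariates. With the median over markers, enterocyte levels were at 0.03 for fasting at 4 weeks and 0.40 for age in fed piglets, eosinophil and mast cell levels at −0.14 at 4 weeks and fibroblast levels at −0.05 for age in fed piglets. The similarity of the fasting responses was −0.008 over genes with a mean log2 CPM of at least 1. No paired analysis was run, although neighbouring pig numbers held 1 fed and 1 fasted pig, because the labels named no pairs. At these depths the smallest simulated changes were recovered in 8 to 34% of genes. The simulation held far fewer changed genes than were called in the real data, so these rates need not carry over, and small changes may have been missed.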

Other observations

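The genes in this part were chosen after their values were seen, no test of an explanation was run on them, and each value comes from the same edgeR fit. The ferrous iron importer SLC11A2 was at 186 ± 77.0 CPM in fed and 38.8 ± 13.9 CPM in fasted 4-week piglets (log2 fold change −2.26, SE 0.16, adjusted p = 1.7e-19) and fell by 1.04 on the log2 scale at 6 weeks (SE 0.15, adjusted p = 1.7e-07). The iron exporter SLC40A1 (−2.21, SE 0.26, adjusted p = 8.7e-11) and the haem-degrading HMOX1 (−2.38, SE 0.2, adjusted p = 2.7e-16) fell at 4 weeks, where HMOX1 rose by 0.76 at 6 weeks (SE 0.19, adjusted p = 0.0011). The milk-associated iron binder LTF went from 35.1 ± 24.0 to 3.13 ± 2.07 CPM at 4 weeks (−3.48, SE 0.49, adjusted p = 7e-09) and was at −0.02 at 6 weeks. Among calcium genes, the vitamin D receptor VDR fell at both ages (−1.12, SE 0.13, adjusted p = 1.2e-11 at 4 weeks and −1.21, SE 0.13, adjusted p = 4.3e-11 at 6 weeks), as did its target S100G (−1.48 and −1.15, SE 0.19 each).

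The clock and glucocorticoid lists were called in no comparison, and only 3 of their genes are given. The clock output gene DBP was at −3.16 for fasting at 4 weeks (SE 0.33, adjusted p = 1.2e-12) against 0.39 at 6 weeks (adjusted p = 0.31), the clock activator BMAL1 at 1.33 (SE 0.14, adjusted p = 4.9e-13) against 0.17 (adjusted p = 0.31) and the glucocorticoid-induced FKBP5 at 1.31 (SE 0.12, adjusted p = 1.1e-14) against 0.03 (adjusted p = 0.83). In the same order of genes, the interaction values were 3.55, −1.16 and −1.28. The hour of sampling was not given in the labels used here.

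Levels of 4 fuel genes are given without a test of fed 4-week against fasted 6-week piglets. The glucose-releasing G6PC1 was at 432 ± 134 CPM in fed 4-week, 440 ± 329 CPM in fasted 4-week, 60.8 ± 41.9 CPM in fed 6-week and 347 ± 130 CPM in fasted 6-week piglets, and PDK4 at 84.9 ± 28.4, 107 ± 58.5, 6.86 ± 2.72 and 73.8 ± 31.3 CPM in the same order. PCK1 was at 909 ± 419 CPM in fed 4-week and 1780 ± 739 CPM in fasted 6-week piglets, and CPT1A at 325 ± 99.9 and 123 ± 36.7 CPM. The starch-digesting MGAM went from 274 ± 190 CPM in fed 4-week to 4690 ± 1380 CPM in fed 6-week piglets (log2 fold change 4.10, SE 0.28, adjusted p = 1.2e-19), and rose with fasting at 4 weeks (2.30, SE 0.26, adjusted p = 2.1e-11). The asparagine synthetase ASNS rose with fasting at 4 weeks (1.95, SE 0.24, adjusted p = 2.5e-10) and fell at 6 weeks (−1.55, SE 0.24, adjusted p = 4.4e-07).

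The antibody transporter PIGR (3.33, SE 0.38, adjusted p = 2.6e-11), the antibody joining chain JCHAIN (3.75, SE 0.47, adjusted p = 4.2e-10), the oxidase DUOX2 (4.38, SE 0.51, adjusted p = 4.1e-11), the nitric oxide synthase NOS2 (3.66, SE 0.53, adjusted p = 1.6e-08), the macrophage receptor CD163 (4.52, SE 0.53, adjusted p = 4e-11) and the crypt gene OLFM4 (3.30, SE 0.42, adjusted p = 7.3e-10) were higher in fed 6-week than in fed 4-week piglets. With fasting at 4 weeks, a comparison that uses the same fed 4-week pigs, they rose by 1.78, 2.17, 1.26, 3.09, 4.18 and 2.59 in that order (largest adjusted p = 0.027, for DUOX2). The endocytic MAMDC4 of the suckling enterocyte was at −2.87 (SE 0.26, adjusted p = 1.1e-14) and the hormone gene MLN at −4.35 (SE 0.5, adjusted p = 2e-11) for age in fed piglets, and neither passed for fasting at 4 weeks (0.10, adjusted p = 0.74, and −0.46, adjusted p = 0.3).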
